A study of Mus musculus with 22 samples.

How the data were processed

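The deposited data were 3 tables of normalised read counts, 1 per gene and library, which the labels call normalised counts. Per the submitters' processing notes, STAR 2.4.2a, Salmon 0.8.2 and DESeq2 were used with the mouse build mm10; which tool did which step was not stated. The deposited values are a signal on a read count scale that the authors had already made comparable between the libraries of each table, so values were never compared between tables. Each table held 48440 genes by Ensembl identifier, of which 48058 matched the GENCODE M21 annotation of mm10, and symbols, biotypes and positions came from that match. The tables also held 2 columns that belong to another series, and these were not used.

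Whole read counts were not recoverable. Low values should be multiples of 1 step per library if a single size factor had been applied, but between 58.6% and 81.6% of them (values up to 20 steps) lay within 0.1 step of a whole multiple, and 95% was required. A count model was therefore not fitted. The approximate number of counted reads per library was taken as the total divided by the commonest smallest step, and carries no counting interval. Counting errors per gene are for the same reason not given, and errors are the spread between libraries.

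Per the labels' protocols, mice were killed by cervical dislocation, the regions were taken as 1 mm punches from 1 mm slices, RNA was extracted with a column kit, and libraries were made from 100 ng of total RNA with a stranded mRNA kit. Whether counting used the strand was not stated, so overlapping antisense genes cannot be separated, and reads of near-identical genes may have been split between them. All mice were male. Per the series' design text there were 3 biological replicates in each group, and the authors included sequencing batch as a covariate. The third high performer of PFC and of mdTH belongs to another series, which leaves 2 libraries in those groups here.

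The 3 tables were tested with limma 3.58.1 (R 4.3.3) on log2(normalised count + 1), with moderated variances (trend and robust), two-sided, Benjamini-Hochberg (BH) adjustment over the genes tested and a threshold of 0.05. Genes with a mean of at least 10 over the libraries of a comparison were tested. Because of the added 1, log2 fold changes understate changes of genes with low values. The ventral tegmental comparison had batch as a covariate. High performer 2 was alone in its batch there, so it added nothing to that contrast, and the means and SDs given for this region leave it out. Means ± SD are of normalised counts, and standard errors (SE) are of log2 fold changes unless stated otherwise. The p-values of single genes measure the spread between these mice. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots.

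The design, the gene lists, the rule for named genes and all but 5 of the alternative settings were fixed before the data were examined. Named genes were Homer1 and, among genes with adjusted p under 0.05, groups that did not overlap in any library, a mean of at least 50 in a group and a symbol that is not a predicted gene, clone or pseudogene, the 10 with the largest rise and the 10 with the largest fall. Up to 4 passing members per list by smallest p were added. Where fewer than 5 genes passed in a direction, the genes with the smallest raw p filled up to 5 and are given as not passing. For the comparison of regions the text gives large changes and examples from the lists. A few genes that the rule named are not reported here.

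Gene lists for synaptic, signalling, stress and housekeeping pathways and for marker genes of brain cell types were tested with limma's camera function at a preset correlation of 0.01, with BH adjustment over the 32 lists that had at least 5 tested members. The genes within 5 Mb of Homer1 formed 1 of these lists. Camera with a correlation estimated per list and limma's fry function were run beside it. Fry tests whether a list's genes move, on balance, in 1 direction and does not compare them with other genes. At the preset correlation camera treats the genes of a list as nearly independent, so its p-values do not measure the spread between mice. Marker lists describe bulk tissue RNA, not counted cells, and a list's test describes its genes in these libraries. In every list that passed, the median and mean log2 fold change and the test had the same sign.

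No 2 libraries of a group held the same values: Pearson correlations of log2 values within groups were 0.906 to 0.982. Replicate numbers did not pair mice across groups. After removing group means, same-number libraries correlated at -0.17 to -0.05 in the CC lines, -0.06 to -0.02 in mdTH, -0.04 to 0.01 in PFC and -0.06 to 0.01 in VTA. The PFC and VTA libraries of the DO mice, in contrast, came from the same 5 mice, and libraries of the same mouse correlated at 0.21 to 0.34 against -0.34 to 0.03 for other pairs. With the mouse as a block, 6528 genes passed between the regions instead of 5260, and 0 with and without the block for the difference between the regions in the effect of performance.

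On simulated values with the means and spread of the CC libraries and 200 changed genes (17186 genes), the limma test found 7.7% of genes changed 1.5-fold, 44.4% of those changed 2-fold and 86.9% of those changed 4-fold, and 8 of 94 calls were unchanged genes. For mdTH (17322 genes) the shares were 20%, 56.9% and 78.1%, with 16 unchanged genes among 116 calls. For PFC of DO mice (17708 genes) they were 14.3%, 38.5% and 75.8%, with 14 among 95. For VTA (17919 genes) they were 0%, 6.3% and 60%, with 4 among 47. For the regions (18027 genes) they were 21.2%, 45.5% and 75.4%, with 8 among 101. For the difference between regions (18050 genes) they were 1.6%, 10.6% and 48.4%, with 3 among 41. The share of unchanged genes among calls was above the nominal 5% in all 6 simulations and highest for PFC and mdTH, so single calls at the threshold there need caution. The list of oligodendrocyte markers, raised 1.5-fold in each simulation, ranked first with 0 other lists passing at the preset correlation. Simulated genes varied independently of each other, so this cannot show how often lists pass falsely when genes vary together. With an estimated correlation its adjusted p was 0.0141 for the CC lines, 0.0536 for mdTH, 0.105 for PFC, 0.305 for VTA, 0.000821 for the regions and 0.0207 for the difference between regions, so a real shift of this size can miss the threshold under that setting.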

Results

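Brain RNA was sequenced from male mice with high or low prepulse inhibition (PPI), the damping of a startle response by a weaker stimulus given just before it. Diversity Outbred (DO) mice, an outbred population in which every animal carries its own mix of founder alleles, gave prefrontal cortex (PFC), ventral tegmental area (VTA) and mediodorsal thalamus (mdTH). Collaborative Cross (CC) lines are inbred lines bred from the same founder strains, and PFC was taken from CC083, the line with high PPI, and CC025, the line with low PPI. The study's title names Homer1, which encodes a scaffold protein of excitatory synapses, as a modifier of attention, so Homer1 was followed in every comparison.

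The series holds 22 libraries in 8 groups. There were 3 libraries each for CC083, CC025, VTA of high performers, VTA of low performers, PFC of low performers and mdTH of low performers, and 2 each for PFC and mdTH of high performers. The CC025 libraries held about 33.2 M to 77.9 M counted reads (M for mega), the CC083 libraries 34.2 M to 49.9 M, the mdTH libraries 59.4 M to 72.6 M, and the PFC and VTA libraries of DO mice 58.8 M to 80.6 M. Between 22102 and 25565 genes had a value above 0 per library. The 2 mitochondrial ribosomal RNAs took 24.6% to 40.68% of the signal in the CC libraries and 27.93% to 37.54% in the PFC and VTA libraries sequenced together. They took only 0.42% to 0.67% in mdTH and 0.68% in VTA high performer 2, which was sequenced in another batch. No comparison sets these classes of library against each other, apart from VTA high performer 2, which the batch term absorbs.

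Homer1 (ENSMUSG00000007617, mm10 chromosome 13, 93299635 to 93405129, plus strand) was lower in PFC of high-performing DO mice and of CC083, the high-PPI line. In DO mice its normalised count was 8461 ± 1405 (SD, n = 2) in high performers and 22546 ± 1252 (n = 3) in low performers, 2.68-fold lower (log2 fold change -1.42, SE 0.13, limma with BH adjustment, adjusted p = 0.00548). Homer1 had the 4th smallest p of 18263 genes tested there, and only the 268th of 17659 in the CC lines. In the CC lines it was 7386 ± 954.7 in CC083 and 13066 ± 94.26 in CC025 (n = 3 each), 1.78-fold lower (log2 fold change -0.83, SE 0.13, adjusted p = 0.00757 by the same test). In both comparisons every high-PPI library lay below every low-PPI library. An exact two-sided permutation test on Homer1 alone gave p = 0.1 for each, the smallest value these group sizes allow.

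In VTA the Homer1 values were 1577 ± 290.7 (n = 2) in high and 2730 ± 915.5 (n = 3) in low performers, a difference that did not pass (log2 fold change -0.75, SE 0.29, limma p = 0.0352, BH-adjusted p = 1; exact permutation p = 0.2). In mdTH they were 2258 ± 268.3 (n = 2) and 1994 ± 315.7 (n = 3), within the spread between mice (log2 fold change 0.19, SE 0.16, BH-adjusted limma p = 0.718; exact permutation p = 0.4). Every VTA library of high performers also lay below every VTA library of low performers (969 to 1783 against 2056 to 3772). The value of 969 belongs to high performer 2 of the other batch. The tables give 1 value per gene, so the short and long Homer1 isoforms could not be separated. The CC call passed in all 16 alternatives. The DO PFC call was lost without low performer 1 (log2 fold change -1.38, adjusted p = 0.0832 in limma) and in 4 other alternatives, whose values range from -1.46 to -1.24 with adjusted p = 0.11 to 0.634.

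**Figure D1:**
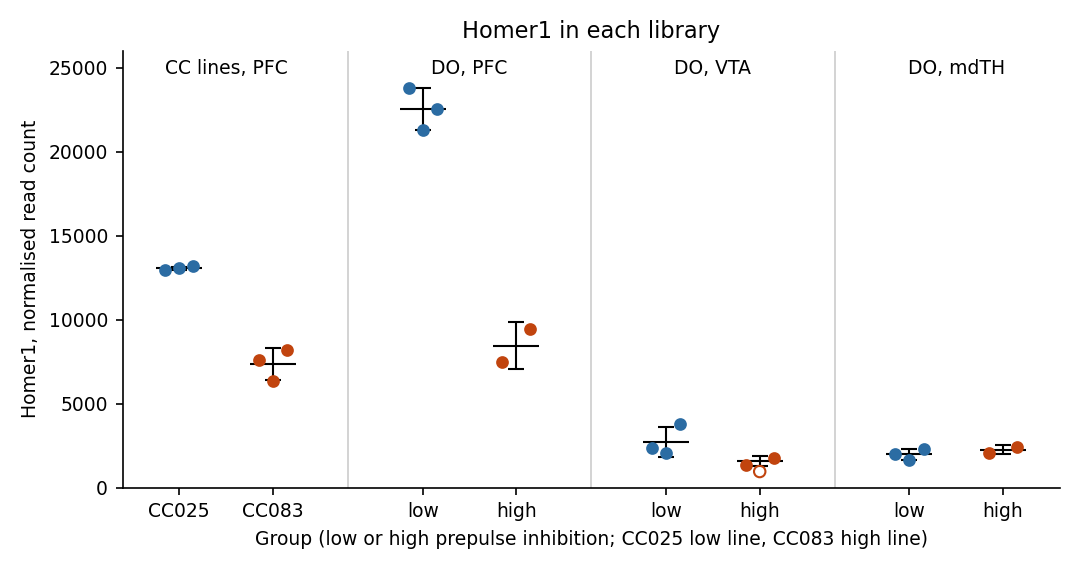
Normalised read count of Homer1 (y axis, linear, from 0) in each library, by group (x axis), with points for libraries and black bars for the group mean ± SD; the open circle is VTA high performer 2, which the mean leaves out. In PFC all high-PPI libraries lie below all low-PPI libraries, at 7467 and 9454 against 21292 to 23797 in DO mice and 6344 to 8220 against 12980 to 13167 in the CC lines.

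High and low performers among the DO mice were compared in PFC to ask which genes differ with PPI in an outbred population. The oligodendrocyte markers Cnp, Mal, Ermn and Tspan2 rose in high performers, though each was called in only 1 of 5 fits that left out a library, and Bdnf, Nptx2 and Homer1 were among the genes that fell. Cnp, an enzyme of myelin, was at 8501 ± 257.7 in high and 4011 ± 312 in low performers (log2 fold change 1.09, SE 0.12, limma with BH adjustment, adjusted p = 0.0173). Mal, a myelin membrane protein, was at 10560 ± 259.3 against 4753 ± 787.1 (1.17, SE 0.15, adjusted p = 0.0425). Bdnf, the neurotrophin gene induced by neuronal activity, was at 921.9 ± 67.27 against 2689 ± 204.6 (-1.54, SE 0.14, adjusted p = 0.00673). Nptx2, which encodes a secreted protein that clusters AMPA receptors, was at 1194 ± 126.8 against 3728 ± 53.66 and fell most among the named genes (-1.65, SE 0.13, adjusted p = 0.00476).

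Of 18263 genes tested, 24 passed in DO PFC, 11 higher and 13 lower in high performers, and 19 of them differed at least 2-fold. The other named genes that rose were Htr2c, the serotonin 2C receptor (2562 ± 58.62 against 940.5 ± 152.6, log2 fold change 1.46), Tmem88b (1.40), Ermn and Bcas1, both of oligodendrocytes (1.23 and 1.21), Ttyh2 (1.17), Gpr37 (1.15), the alarmin gene Il33 (1.05), Zmat4 (0.87) and Tspan2 (0.86). The others that fell were Acvr1c, an activin and nodal receptor (-1.43), Syt17 (-1.33), Grasp, a scaffold partner of group I metabotropic glutamate receptors (-1.12), Hs3st2 (-0.98), Peak1 (-0.92) and Enc1 (18560 ± 1806 against 31730 ± 2002, -0.78), which lies within 5 Mb of Homer1. Adjusted p was between 0.0253 and 0.0436 for all of these by limma with BH adjustment. Outside the naming rule, and picked after their values were seen, the pseudogenes Rps6-ps4 and Amd-ps3 and the predicted genes Gm15772 and Gm20458 also passed. They may share reads with related genes, which was not tested for them.

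All 24 oligodendrocyte markers tested were higher in PFC of high performers, with a median log2 fold change of 1.14. Of them 4 rose over all genes tested (Cnp, Mal, Ermn and Tspan2) and 22 rose when adjusted over the list alone. Mbp, the myelin basic protein gene, had 1.24 without passing (adjusted p = 0.114 in limma). The list as a whole rose (limma camera, BH-adjusted p = 1.1e-21; adjusted p = 0.461 with an estimated correlation and 0.0862 with fry). The oligodendrocyte score, the mean log2 value of the list, was 11.51 and 11.46 in the high performers and 10.08, 10.37 and 10.68 in the low performers. Astrocyte markers had 19 of 21 positive values and a median of 0.18 (camera adjusted p = 0.0211; adjusted p = 0.518 with an estimated correlation), with 0 members passing.

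Lists of the glutamate synapse fell in PFC of high performers. In the Homer and postsynaptic scaffold list 22 of 24 members were lower (median -0.28), Homer1 fell over all genes tested and 8 fell adjusted over the list alone. Baiap2, another scaffold gene, was at 8737 against 13680 (-0.64) without passing (limma with BH adjustment, adjusted p = 0.0887). The camera test gave adjusted p = 0.000107 for this list (adjusted p = 0.461 with an estimated correlation). Ionotropic glutamate receptor genes were lower in 20 of 28 (median -0.26, camera adjusted p = 0.00139; adjusted p = 0.461 with an estimated correlation; fry adjusted p = 0.0346). Grin2b, an NMDA receptor subunit, had 23190 ± 1172 against 36740 ± 4036 without passing (-0.66, adjusted p = 0.073 in limma). Group I mGluR signalling genes were lower in 16 of 21 (median -0.28, camera adjusted p = 0.0126; adjusted p = 0.461 with an estimated correlation), and 1 fell adjusted over the list alone. Presynaptic release genes were lower in 23 of 33 (median -0.18, camera adjusted p = 0.022; adjusted p = 0.461 with an estimated correlation), where 2 rose and 8 fell adjusted over the list alone.

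Activity-induced early genes fell as a list in DO PFC, with 26 of 37 lower (median -0.36, camera adjusted p = 0.000107; adjusted p = 0.588 with an estimated correlation). Bdnf and Nptx2 fell over all genes tested and 8 members fell adjusted over the list alone. Egr3, an activity-induced transcription factor, was at 970.6 against 2402 without passing (-1.28, limma with BH adjustment, adjusted p = 0.0672). Heat shock and unfolded protein genes were lower in 23 of 28 (median -0.23, camera adjusted p = 0.00139; adjusted p = 0.518 with an estimated correlation). Oxidative phosphorylation genes were higher in 61 of 68 (median 0.14, camera adjusted p = 9.86e-05; adjusted p = 0.461 with an estimated correlation) and cytosolic ribosomal protein genes in 53 of 75 (median 0.08, camera adjusted p = 0.00842; adjusted p = 0.518 with an estimated correlation). In these last 3 lists no member passed over all genes tested.

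Choroid plexus RNA differed widely between the PFC libraries of DO mice. Ttr, the abundant secreted protein gene of choroid plexus, was at 134471.3 in high performer 1, 8900.6 in high performer 3 and 38188.9 in low performer 3, against 57.5 and 310.6 in low performers 1 and 2. The choroid plexus list was higher in 16 of 18 members (median 2.62, camera adjusted p = 0.00098; adjusted p = 0.588 with an estimated correlation) with 0 passing. Without both libraries with the most of this RNA, an alternative chosen after seeing the data, 30 genes passed, of which only 6 were among the 24. Homer1, Nptx2 and Cnp were still called, but the other 17 named genes were not, among them Bdnf, Mal and Htr2c (adjusted p = 0.0732 each in limma). Their log2 fold changes stayed similar (-1.47, 1.25 and 1.56) in this fit of 1 against 2 libraries. The mean log2 value of the choroid plexus list was still 7.87 in high performer 3 against 4.69 and 5.14 in low performers 1 and 2. The fit therefore cannot show whether these changes are free of choroid plexus RNA. The lists of activity-induced, heat shock, presynaptic and oxidative phosphorylation genes were not called in it (adjusted p = 0.538, 0.212, 0.0715 and 0.0715 by limma camera with BH adjustment).

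With 2 against 3 mice, DO PFC counts rest on few libraries. The count of 24 became 1 without low performer 1 (Gm15772, a predicted gene), 7 without low performer 2 and 86 without low performer 3. Of the 20 named genes Homer1, Bdnf and Nptx2 were called in 4 of the 5 fits that left out a library, Acvr1c in 2, Grasp in 0 and the other 15 in 1. For the oligodendrocyte genes Cnp, Mal, Ermn and Tspan2 that fit was the 1 without low performer 3. Without high performer 1 activity-induced and heat shock lists were not called (camera adjusted p = 0.392 and 0.0908 in limma), without high performer 3 the mGluR, presynaptic, ribosomal and astrocyte lists (0.075, 0.208, 0.123 and 0.563), and without low performer 1 these same lists (0.0887, 0.118, 0.104 and 0.0887). Quantile scaling ended the calls of the mGluR and presynaptic lists (0.0517 and 0.176). In DO PFC a raw p under 0.05 was found for 1841 genes against 913 by chance, and 28.1% of genes had groups that did not overlap against 20% by chance.

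**Figure D2:**
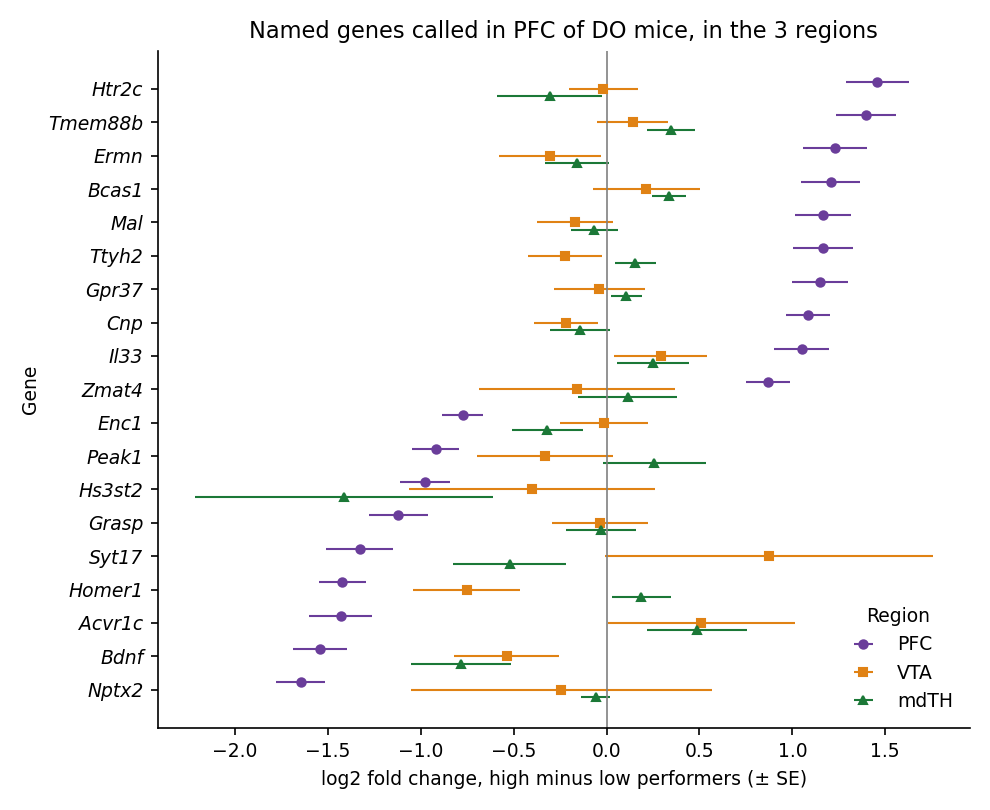
Log2 fold change, high minus low performers (x axis, points with ± SE bars), of 19 of the 20 genes named in PFC of DO mice, all but Tspan2 (y axis), in PFC (circles), VTA (squares) and mdTH (triangles). Oligodendrocyte genes such as Cnp lie above 0 in PFC (1.09), and Homer1 lies at -1.42 in PFC, -0.75 in VTA and 0.19 in mdTH.

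The CC lines were compared to ask which genes differ in PFC between an inbred line with high and one with low PPI. The 3 mice of a line share their genotype. With 1 line at each level, an effect of PPI cannot be told apart from any other difference between the lines. The lines differed at many genes, some with counts near 0 in 1 line. Crym, which encodes a thyroid hormone binding protein, was at 1393 ± 120.6 in CC083 and 65.54 ± 21.8 in CC025 (log2 fold change 4.44, SE 0.245, limma with BH adjustment, adjusted p = 1.27e-05). Sec61g, a subunit of the protein translocation channel, was at 1133 ± 217.7 against 43.03 ± 11.25 (4.70, SE 0.24, adjusted p = 7.19e-06), and Pon2, a paraoxonase, at 461.4 ± 147.6 against 21.87 ± 6.696 (4.33, SE 0.32, adjusted p = 5.68e-05). Tac1, the substance P precursor, was at 462.8 ± 238.2 against 110.3 ± 3.405 (1.95, SE 0.31, adjusted p = 0.00817). H2-K1, a classical MHC class I gene, was at 125.7 ± 15.4 against 423.6 ± 87.09 (-1.73, SE 0.21, adjusted p = 0.00154).

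Of 17659 genes tested, 654 passed, 329 higher and 325 lower in CC083, and 496 of them differed at least 2-fold. The remaining large rises were Zfp605 (541.5 ± 38.71 against 2.32 ± 2.88, log2 fold change 7.75), Prss56 (7.32), Ifit1bl1 (5.47), Sds, the serine dehydratase gene (5.42), Zfp973 (4.94), Cyp4f14 (4.55) and Ugt1a6a (4.42). The large falls were Hist1h3f (0.685 ± 1.19 against 213.7 ± 50.55, -7.19), Lpcat2b (1.63 ± 1.465 against 323.2 ± 32.26, -7.15), the chemokine gene Ccl28 (-6.31), Zfp738 (-5.95), Fam205c (-5.53), Tmem267 (-5.39), Tmprss6 (-5.10) and Tlr1, a toll-like receptor gene (-4.45). Ubash3a and Cldn34c1 were listed at 0 in all 3 CC083 libraries, against 127.7 ± 24.49 and 104.2 ± 24.33 in CC025. Adjusted p for these genes was at most 0.0025 in limma with BH adjustment, and all 20 genes with the largest changes passed in each of their alternatives. Several belong to families with near-identical copies (zinc finger, histone, Ugt1a and Fam205 genes), so their levels are uncertain. Whether reads of 1 line were lost against the mm10 reference was not tested for the genes called between the lines.

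**Figure D3:**
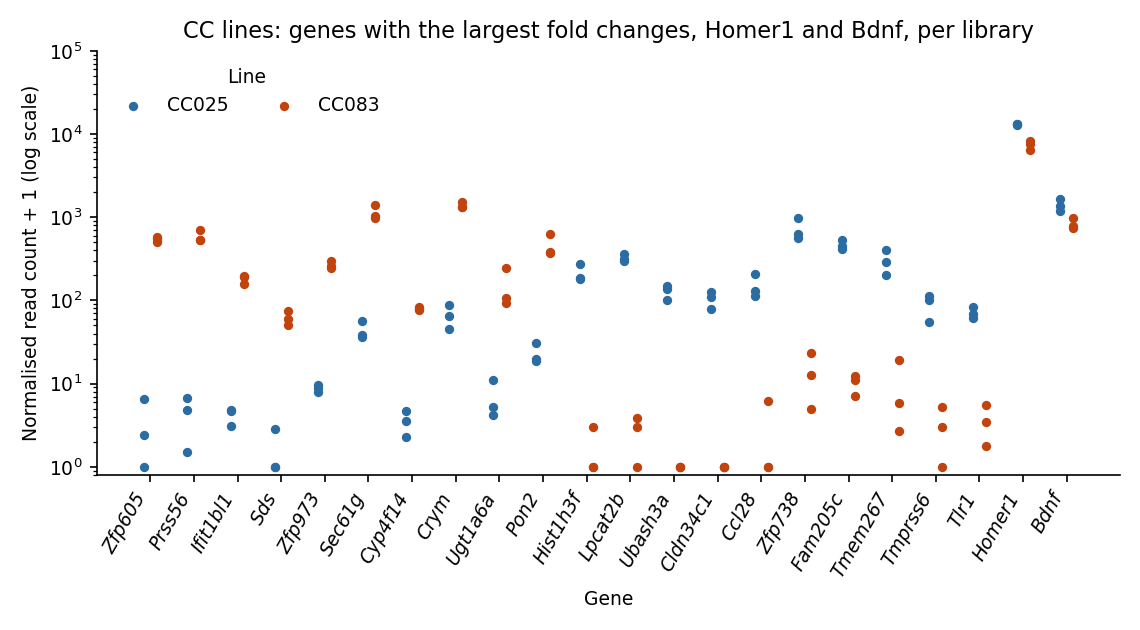
Normalised read count + 1 (y axis, log scale) in each PFC library of CC025 and CC083 (colours) for the 20 genes with the largest fold changes and for Homer1 and Bdnf (x axis); each point is a library. The lines do not overlap for these 20 genes, and Homer1 differs less, at 6344 to 8220 in CC083 against 12980 to 13167 in CC025.

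Activity-induced early genes fell as a list in CC083, with 33 of 37 members lower and a median log2 fold change of -0.62 (limma camera, BH-adjusted p = 6.99e-07; adjusted p = 0.864 with an estimated correlation). Bdnf fell over all genes tested (834.3 ± 130.1 against 1408 ± 230, -0.75, SE 0.17, adjusted p = 0.0417), and 13 members fell adjusted over the list alone. Egr1, an activity-induced transcription factor, was at 4313 ± 897.4 against 7190 ± 1023 (-0.75, adjusted p = 0.0504 in limma), and Arc, a plasticity gene of dendrites, at 4929 ± 2007 against 12340 ± 4489 (-1.33, adjusted p = 0.113), neither of them passing. The Bdnf call was lost under both other scalings (adjusted p = 0.0649 and 0.0525) and in 5 of 6 fits that left out a library, all but that without CC083 replicate 3.

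Immune gene lists fell in CC083, though the MHC, interferon and microglia lists were not called without CC025 replicate 1. Of 19 MHC class I genes, 6 fell over all genes tested, and 1 rose and 7 fell adjusted over the list alone (median -0.41, camera adjusted p = 0.0164; adjusted p = 0.864 with an estimated correlation). Beside H2-K1 these included H2-Q6, H2-Q7 and H2-Bl (-3.12, -3.41 and -3.58), whose sequences are so alike that reads may be shared between them. Interferon response genes were lower in 24 of 28 (median -0.73, camera adjusted p = 0.000494; adjusted p = 0.864 with an estimated correlation), where Ifit2 fell (488.5 ± 102.6 against 980.2 ± 101.2, -1.02, adjusted p = 0.0149 in limma; 0.0566 without CC025 replicate 3) and 1 rose and 6 fell adjusted over the list alone. Ifit3, of the same family, had 316.7 against 79.06 in the opposite direction without passing (2.38, adjusted p = 0.0841). Microglia markers were lower in 15 of 21 (median -0.34, camera adjusted p = 0.00678; adjusted p = 0.864 with an estimated correlation), with C1qa at 424.1 against 757.4 (-0.83, adjusted p = 0.0542 in limma) and 4 that fell adjusted over the list alone.

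Vascular and meningeal markers were lower in CC083 as well. Endothelial and mural markers were lower in 20 of 23 (median -0.71, camera adjusted p = 0.000494; adjusted p = 0.864 with an estimated correlation), and Rgs5, a pericyte gene, fell (1367 ± 98.47 against 3085 ± 1122, -1.12, adjusted p = 0.0253 in limma). The Rgs5 call was lost under quantile scaling (0.0525), without trend or robust variances (0.104) and without CC083 replicate 1, 2 or 3 (0.0942, 0.113 and 0.0678). All 17 meningeal fibroblast markers were lower (median -0.90, camera adjusted p = 0.0449; adjusted p = 0.957 with an estimated correlation), 0 of them passing. Col3a1, a fibroblast collagen, was at 49.14 ± 16.21 against 1026 ± 1236 (-3.20, adjusted p = 0.343 in limma). The meningeal score was 11.08 in CC025 replicate 1 and 6.77 to 8.58 in the other 5 libraries. Without CC025 replicate 1 the meningeal list was not called and turned its direction (camera adjusted p = 0.863). Choroid plexus RNA stood out in CC083 replicate 3, with Ttr at 17068.2 against 107.8 to 399.2 in the other 5 and a choroid plexus score of 7.56 against 4.5 to 5.73, and without this library 12 lists passed, 7 of the 8 among them. Heat shock genes were lower in 24 of 28 (median -0.27, camera adjusted p = 0.000255; adjusted p = 0.864 with an estimated correlation), with 1 that rose and 10 that fell adjusted over the list alone. Striatal projection neuron markers were higher in 17 of 18 (median 0.50, camera adjusted p = 0.0134; adjusted p = 0.864 with an estimated correlation), where Tac1 rose.

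Among lists that did not pass in the CC lines, single members changed. Of 33 presynaptic genes, Sv2c (log2 fold change 0.86) and Syn3 (0.76) rose and Rab3c fell (-0.83), with adjusted p of 0.0253 to 0.0294 in limma. Ndufs5, a subunit of respiratory complex I, fell (657.7 ± 106.4 against 1537 ± 154.6, -1.23, adjusted p = 0.00198), as did the mitochondrial transcripts mt-Rnr1 (-0.98) and mt-Cytb (-0.75), while mt-Nd2 rose (0.62); the mt-Rnr1 difference was 0 under quantile scaling. Rps3a1, Rpl21 and Rpl34 fell (-1.06, -0.83 and -0.89) and Rps2 rose (0.60), all with many pseudogene copies. Camk4, a calcium and calmodulin dependent kinase gene, rose (0.56, adjusted p = 0.0493), Cdkn1a fell (-1.07) and the cilia gene Rsph1 fell (-2.23). Most of these list members rest on few libraries. Camk4 passed in 5 of 16 alternatives and in none of the 6 fits that left out a library (adjusted p = 0.0632 to 0.214). In such fits mt-Cytb passed only without CC025 replicate 2, and mt-Nd2 and Rps2 only without CC025 replicate 1, and mt-Cytb was also lost under 75th percentile scaling (0.0569). The mt-Rnr1 call held only without CC025 replicate 1 or 2, Sv2c without CC025 replicate 2 or CC083 replicate 1, Rab3c without CC025 replicate 1 or CC083 replicate 1, and Syn3 without CC025 replicate 1 or CC083 replicate 3. Cdkn1a was lost without CC025 replicate 2 (0.0992) or CC083 replicate 1 or 2 (0.0748 and 0.0743), and Rpl34 without CC025 replicate 2 (0.0524). Within 5 Mb of Homer1, 64 genes were tested, of which 2 rose (Sv2c and AW495222, at 0.86 and 2.04) and 2 fell (Homer1 and Gm8546, at -0.83 and -3.95) (AW495222 and Gm8546 are poorly annotated genes, and AW495222 was called in 1 of 6 fits that left out a library, that without CC083 replicate 2). As a list these 64 genes did not move (median -0.04, camera adjusted p = 0.848).

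Of the 654 calls, 245 (37.5%) were predicted genes or pseudogenes, against 19.9% of the genes tested. With these left out before testing, an alternative chosen after seeing the data, 316 genes passed, and the count was 403 at a mean of at least 100. It was 351 without CC025 replicate 2, 392 without CC083 replicate 2 and 435 without CC083 replicate 1. Without CC025 replicate 1 the MHC, interferon, microglia and meningeal lists were not called (limma camera, BH-adjusted p = 0.354, 0.642, 0.097 and 0.863), and the meningeal list turned its direction. Without CC083 replicate 2 the MHC, striatal and meningeal lists were not called (0.0996, 0.707 and 0.0761), and the meningeal list was not called without CC083 replicate 1 (0.192) or 3 (0.0515) either. A raw p under 0.05 was found for 2708 genes against 883 by chance, and groups did not overlap for 21.6% of genes against 10% by chance.

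The CC and DO comparisons of PFC share no library, which allows the direction of a gene to be compared between them. Homer1 and Bdnf passed in both and fell in both, against 0.86 genes called in both by chance. Whether these 2 genes exceed chance was not tested, and the CC call of Bdnf held in 1 of 6 fits that left out a library. Of the 607 genes called in the CC lines and tested in DO mice, 320 (52.7%) had the same sign. The other 9 of the 10 splits of the 5 DO libraries into 2 and 3 gave 42.8% to 53.2%, and 1 of them gave as high a share. Over 16904 genes the fold changes correlated at r = 0.019 (Spearman 0.006); this is a correlation across genes, which are not independent replicates.

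High and low performers were compared in mdTH for the same question in a thalamic region. Gpr26, Tacr1, Mdga1 and Htr2a were among 18 genes that fell in high performers, and Jun rose, but of these only Gpr26 was called whichever library was left out. Gpr26, an orphan receptor, was at 190.9 ± 5.796 in high (n = 2) and 2409 ± 348.1 in low performers (n = 3; log2 fold change -3.64, SE 0.15, limma with BH adjustment, adjusted p = 0.0043). Tacr1, the substance P receptor, was at 14.8 ± 6.51 against 501.1 ± 112.6 (-5.03, SE 0.36, adjusted p = 0.0167). Mdga1, a synaptic adhesion gene, was at 160.7 ± 18.67 against 2660 ± 873.8 (-4.00, SE 0.27, adjusted p = 0.0167). Htr2a, the serotonin 2A receptor, was at 14.03 ± 4.707 against 213.4 ± 24.91 (-3.87, SE 0.33, adjusted p = 0.0252). Jun, an activity-induced transcription factor, rose (6014 ± 307.5 against 3063 ± 217.2, 0.98, SE 0.096, adjusted p = 0.0421).

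Of 17623 genes tested, 20 passed in mdTH, 2 higher and 18 lower, and 19 differed at least 2-fold. The other named falls were Cxcl13, a chemokine gene (-4.74), Htr5b, a serotonin receptor gene (-4.41), Nr4a2, a nuclear receptor gene (-3.68), Kctd8, an auxiliary subunit of GABA-B receptors (-3.39), Frmpd3 (-3.32) and Nos1, the neuronal nitric oxide synthase (273 ± 6.817 against 1235 ± 244.7, -2.16), with adjusted p between 0.0252 and 0.0476 by limma with BH adjustment. Wfdc10 was listed at 0 in both high performers against 59.32 ± 7.066. On the higher side 4 genes named to fill up to 5 did not pass, namely Grin2c, an NMDA receptor subunit (8708 against 5043, 0.78, adjusted p = 0.0658), Dusp27 (1.64), Pitpnc1 (0.78) and Rab37 (1.03).

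Marker lists of neighbouring nuclei differed between the mdTH groups. Habenula and hypothalamus markers were lower in 12 of 18 (median -0.62, limma camera with BH adjustment, adjusted p = 0.012; adjusted p = 0.812 with an estimated correlation), and 4 fell adjusted over the list alone. Pou4f1, a habenular transcription factor, was at 35.05 against 877.9 without passing (-5.08, adjusted p = 0.114). Midbrain dopamine neuron markers were lower in 12 of 16 (median -0.36, camera adjusted p = 0.00267; adjusted p = 0.812 with an estimated correlation), with 3 that fell adjusted over the list alone; Calb2, which thalamic midline cells also express, was at 2340 ± 912.5 against 16870 ± 7285 (-2.79, adjusted p = 0.123 in limma). Thalamic markers did not pass (median 0.06, camera adjusted p = 0.0534), and their mean log2 value was 13.14 and 13.25 in high and 13.18, 13.19 and 13.22 in low performers. The habenula score was 6.46 and 5.4 against 6.36, 6.88 and 7.11, and the midbrain dopamine score 7.55 and 7.08 against 8.22, 8.44 and 8.21. Whether the genes called in mdTH differ through RNA of neighbouring nuclei in the punches rather than with performance was not tested.

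Receptor and stress lists changed beside them. Monoamine and acetylcholine receptor genes were lower in 20 of 32 (median -0.17, camera adjusted p = 0.0431; adjusted p = 0.812 with an estimated correlation), where Htr2a fell and 3 rose and 8 fell adjusted over the list alone. Chrm2, a muscarinic receptor gene, had -1.55 (adjusted p = 0.0749 in limma). Homer and postsynaptic scaffold genes were higher in 19 of 24 (median 0.18, camera adjusted p = 0.00829; adjusted p = 0.812 with an estimated correlation), with 4 that rose and 1 that fell adjusted over the list alone; Shank3 was at 60400 against 35470 (0.77, adjusted p = 0.123 in limma). Heat shock genes were lower in 25 of 28 (median -0.29, camera adjusted p = 0.00129; adjusted p = 0.812 with an estimated correlation), with 3 that fell adjusted over the list alone. Circadian clock genes were higher in 15 of 18 (median 0.16, camera adjusted p = 0.0156), oxidative phosphorylation genes in 59 of 68 (median 0.08, camera adjusted p = 0.00239), and ribosomal protein genes lower in 59 of 75 (median -0.08, camera adjusted p = 0.0423). For each of these last 3 lists adjusted p = 0.812 with an estimated correlation, and no member passed.

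The mdTH count of 20 became 8 without high performer 1, 5 without high performer 3, 1 without low performer 1 (Gpr26), 3 without low performer 2 and 11 without low performer 3. The 5 genes were Gpr26, Prokr2, Amd2, Gm12918 and Atp6v0c-ps2 and the 3 were Gpr26, Mdga1 and Rps26-ps1, and of the named genes Gpr26 passed in all 5 of these fits, Mdga1, Nr4a2, Kctd8 and Frmpd3 in 1 each, and Tacr1, Htr2a, Cxcl13, Htr5b, Nos1, Wfdc10 and Jun in 0. Without low performer 2, all lists but heat shock were not called (limma camera, BH-adjusted p = 0.0534 for dopamine markers to 0.461 for ribosomal genes). Without high performer 3, the receptor, oxidative phosphorylation, habenula, circadian and ribosomal lists were not called (0.178, 0.0514, 0.118, 0.113 and 0.0837). Without high performer 1 it was the scaffold, heat shock and ribosomal lists (0.222, 0.124 and 0.274), and without low performer 3 the habenula and ribosomal lists (0.096 and 0.0887). Quantile scaling ended the calls of the scaffold, receptor, oxidative phosphorylation and circadian lists (0.159, 0.0647, 0.185 and 0.0927). A raw p under 0.05 was found for 1983 genes against 881 by chance, and groups did not overlap for 29.5% of genes against 20% by chance.

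In VTA, where midbrain dopamine neurons lie, no gene passed between high and low performers. By limma with BH adjustment 0 of 18487 genes passed and the smallest adjusted p was 0.165, and a raw p under 0.05 was found for 372 genes against 924 by chance. Among genes eligible under the naming rule, which leaves out predicted genes and pseudogenes, those with the smallest p on the higher side were Ubash3a (114.4 against 0.365), Slc25a53 (1109 against 448.4), Olfr287 (443.7 against 170.2), Rpl35a (2629 against 1270) and Catspere2 (1918 against 1183). Among the same eligible genes, those on the lower side were Mael (1.027 against 52.24), Amd2 (279.6 against 1307), Ptk2b, a calcium-activated kinase gene (758.9 ± 75.81 against 1794 ± 529.2), Mybpc1 (9.222 against 62.08) and Lars2, a mitochondrial leucyl-tRNA synthetase gene (876.2 against 3110 ± 1320). All 10 had adjusted p = 1 in limma, and the direction of Catspere2 turned without the batch term.

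Of the lists, 6 passed in VTA at the preset correlation. Midbrain dopamine neuron markers were higher in 19 of 20 (median log2 fold change 0.83, limma camera with BH adjustment, adjusted p = 0.0173) and genes of dopamine synthesis and transport in 17 of 20 (median 0.77, adjusted p = 0.0462). Chrna6, a nicotinic receptor subunit of dopamine neurons, had 12720 ± 3209 against 8649 ± 9839 (1.54, adjusted p = 1). Ionotropic glutamate receptor genes were higher in 21 of 28 (median 0.18, adjusted p = 0.0494). Heat shock genes were lower in 23 of 28 (median -0.23, adjusted p = 0.00258), activity-induced genes in 25 of 36 (median -0.27, adjusted p = 0.0462) and oligodendrocyte markers in 20 of 24 (median -0.21, adjusted p = 0.0462). For all 6 lists adjusted p = 0.921 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone.

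RNA of dopamine neuron markers varied between the VTA libraries. The midbrain dopamine score was 12.38, 12.97 and 11.88 in high performers 1 to 3 and 11.38, 12.84 and 9.72 in low performers 1 to 3. All 6 list calls in VTA were lost without high performer 1 (camera adjusted p = 0.358 to 0.536) and without low performer 3 (0.159 to 0.928), and the oligodendrocyte list then turned its direction. Haemoglobin genes summed to 57206.1 in low performer 2 against 7586.1 to 24179.9 in the other VTA libraries. Under 75th percentile and quantile scaling, heat shock and midbrain dopamine lists passed and the other 4 did not (camera adjusted p = 0.0502 to 0.0622 in limma).

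**Figure D4:**
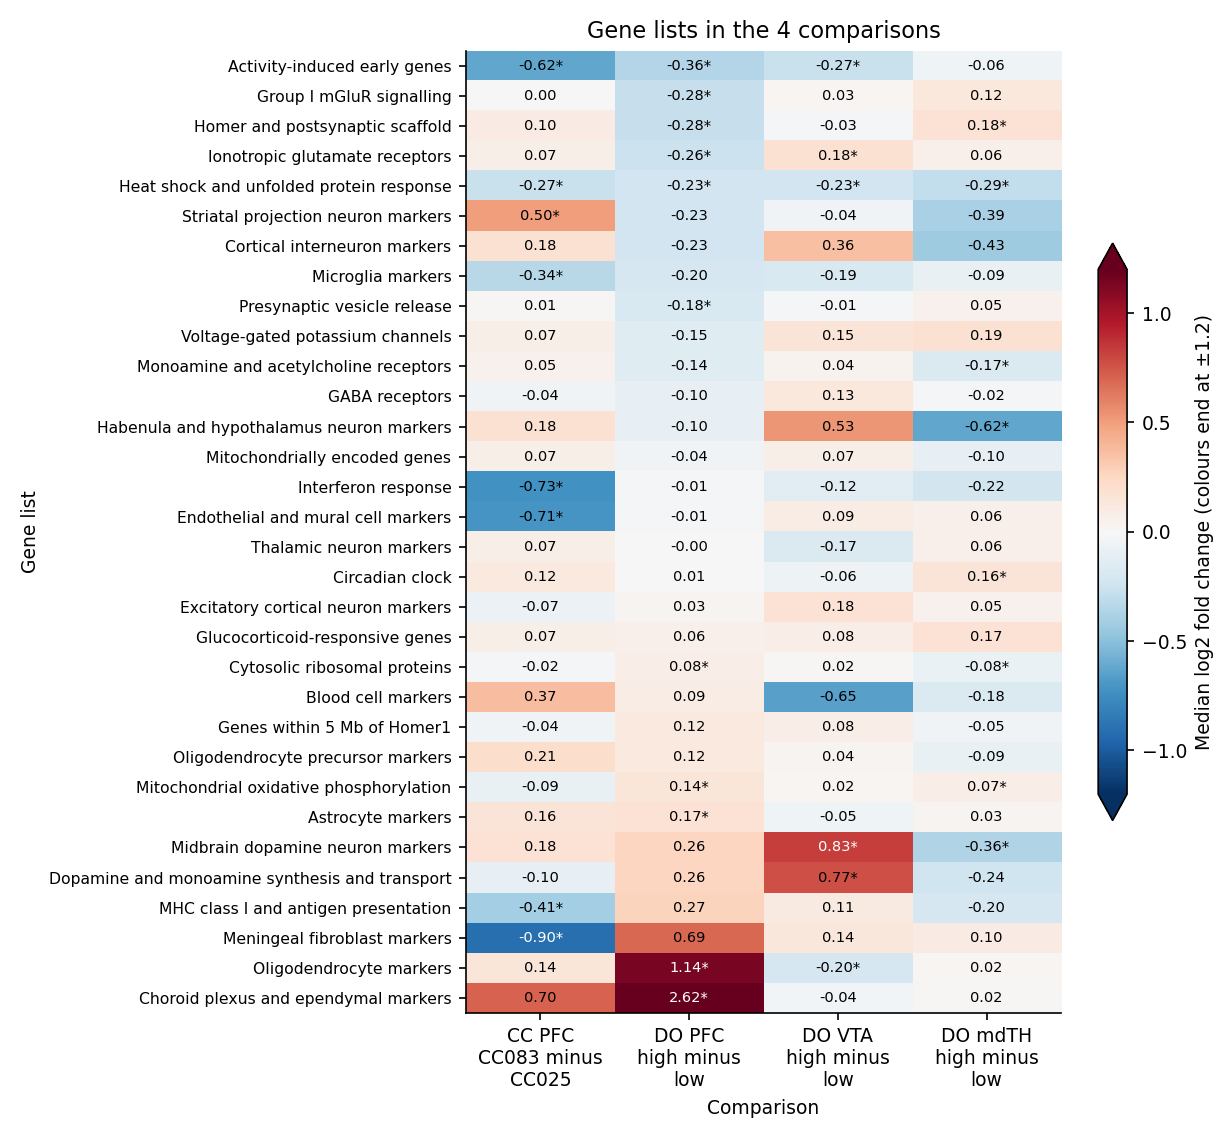
Median log2 fold change of 32 gene lists (y axis), in CC083 minus CC025 and in high minus low performers of each DO region (x axis). Values are shown as numbers and as colours from blue (lower in CC083 or high performers) to red (higher), with colours ending at ±1.2. An asterisk marks a camera adjusted p under 0.05 at the preset correlation. Oligodendrocyte markers stand at 1.14 in PFC of DO mice and at -0.21 in VTA, and activity-induced genes lie below 0 in all 4 columns.

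The fold changes of the DO regions were set side by side. Across genes they correlated at r = 0.336 between mdTH and PFC (16698 genes), 0.293 between mdTH and VTA (16968 genes) and 0.291 between PFC and VTA (17417 genes); the regions come from the same mice and genes are not independent replicates. Gm15772, a predicted gene outside the naming rule and picked after its value was seen, was the only gene called in more than 1 region (mdTH and PFC). Of the mdTH calls, 13 of 18 had the same sign in PFC and 7 of 19 in VTA, and of the PFC calls 13 of 24 had the same sign in VTA.

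VTA and PFC of the same 5 DO mice were compared to describe the dissections. Genes of dopamine neurons marked VTA and genes of cortical projection neurons marked PFC. Slc6a3, the dopamine transporter, was at 64430 ± 47020 in VTA and 2.798 ± 1.769 in PFC (n = 5 each; log2 fold change 13.82, SE 0.75, limma with BH adjustment, adjusted p = 2.16e-06), and Th, which makes the dopamine precursor, at 32210 ± 24250 against 90.07 ± 43.21 (8.08, SE 0.64, adjusted p = 2.23e-05). Tbr1, a transcription factor of deep cortical layers, was at 115.8 ± 55.84 in VTA and 6836 ± 437.7 in PFC (-5.91, SE 0.25, adjusted p = 1.99e-07), and Fezf2, another, at 41.76 ± 16.79 against 2774 ± 252.6 (-6.09, SE 0.26, adjusted p = 1.99e-07). Homer1 itself was at 2269 ± 916 in VTA and 16910 ± 7797 in PFC (-2.76, SE 0.17, adjusted p = 1.6e-06).

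Of 18586 genes tested, 5260 passed between the regions, 2534 higher and 2726 lower in VTA, and 2484 of them differed at least 2-fold. Other large rises were those of En1 (10.66), Slc10a4 (9.24), Chrna6 (8.84), Cnpy1 (8.39), Ddc (7.67), Dlk1 (7.58) and Foxa2 (7.53), most of them genes of midbrain or dopamine neurons. Other large falls were those of Urah (-7.07), Trbc2 (-6.54), Ovol2 (-6.34), Kcnh3, a cortical potassium channel (-5.97), Krt12 (-5.66) and Serpinb8 (-5.59). Adjusted p for these genes was at most 0.00132 in limma with BH adjustment. With raw p under 0.05 there were 7194 genes against 929 by chance, and for 22.9% of genes every VTA library lay on 1 side of every PFC library against 0.8% by chance.

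Of 32 lists, 18 passed between the regions. Midbrain dopamine markers rose in 18 of 20 (median 6.28, limma camera with BH adjustment, adjusted p = 1.65e-14) and dopamine synthesis genes in 16 of 20 with 1 that fell (median 6.28 as well, many members being on both lists). Oligodendrocyte markers rose in 23 of 24 (median 1.69, adjusted p = 1.77e-15), among them Cnp (17500 ± 2441 against 5807 ± 2473, 1.55). For these 3 lists adjusted p = 0.155 with an estimated correlation. Homer and postsynaptic scaffold genes fell in 20 of 24 with 1 that rose (median -1.30, adjusted p = 1.15e-11; adjusted p = 0.105 with an estimated correlation), among them Nrgn (1204 against 27090, -4.52) and Dlgap1 (-2.27). Excitatory cortical markers fell in 16 of 23 with 1 that rose (median -1.87, adjusted p = 1.27e-08; adjusted p = 0.105 with an estimated correlation) and activity-induced genes in 23 of 37 with 2 that rose (median -1.16, adjusted p = 1.29e-08; adjusted p = 0.155 with an estimated correlation), such as Egr3 (43.26 against 1829, -5.32).

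Further region lists went the same ways. Astrocyte markers rose in 13 of 21 with 2 that fell (median 0.48), with Agt, the angiotensin precursor, at 7533 against 151.9 (5.56) and Slc1a2, a glutamate transporter, lower in VTA (-0.98). Oligodendrocyte precursor markers rose in 7 of 12 with 1 that fell (median 0.68). Interneuron markers fell in 11 of 24 with 3 that rose (median -1.19), with Npy at -5.16 and Sst at -3.12 but Calb2 at 4.59. Potassium channel genes fell in 15 of 28 with 2 that rose (median -0.58), circadian genes in 11 of 18 with 1 that rose (median -0.59), group I mGluR genes in 12 of 21 with 1 that rose (median -0.85), presynaptic genes in 18 of 33 with 8 that rose (median -0.66) and ionotropic glutamate receptor genes in 13 of 28 with 4 that rose (median -0.38). Oxidative phosphorylation genes rose in 10 of 68 (median 0.17), ribosomal protein genes in 7 of 75 with 2 that fell (median 0.14), thalamic markers in 10 of 21 with 3 that fell (median 0.86) and habenula and hypothalamus markers in 8 of 19 with 1 that fell (median 1.40). Camera adjusted p was 8.22e-05 to 0.0215 for these 12 lists, and 0 of the 18 lists passed with an estimated correlation (adjusted p = 0.105 to 0.699 with an estimated correlation). Because the regions came from the same mice, the mouse was also fitted as a block, and then 22 lists passed, the 18 among them. The habenula call was lost without VTA high performer 1 (0.15), without VTA low performer 2 (0.0693) and without the 2 PFC libraries with the most choroid plexus RNA (0.0549). Without VTA low performer 2 the thalamic and ribosomal calls were lost too (0.0515 and 0.0645), and the ribosomal list did not pass with fry (0.158). Without those 2 PFC libraries 3334 genes passed between the regions.

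An interaction term asked whether the effect of performance differed between VTA and PFC of the same 5 mice. For no single gene did it pass. By limma with BH adjustment 0 of 18586 genes passed and the smallest adjusted p was 0.783, and a raw p under 0.05 was found for 669 genes against 929 by chance. Among genes eligible under the naming rule, the smallest p on the side of a more positive effect in VTA belonged to Grasp (difference 1.08), Smad3 (1.22), Stard8 (2.07), Col4a1 (1.35) and Csmd2 (1.01), each with adjusted p = 1. On the other side were Cnp (-1.30) and Htr2c (-1.47), with adjusted p = 0.783, and Ttyh2 (-1.39) and Plekhh1 (-1.38), with adjusted p = 0.967. For Homer1 the difference was 0.67 (SE 0.34, adjusted p = 1), so its effect was not shown to differ between the regions. Of the lists, 5 passed at the preset correlation, with oligodendrocyte markers lower in all 24 (median -1.35, limma camera with BH adjustment, adjusted p = 2.51e-28; adjusted p = 0.469 with an estimated correlation), and 18 of them passing adjusted over the list alone.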

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

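Of the tests in this part, the comparison of oligodendrocyte markers in all 3 regions, the test for fewer neurons, the comparison of Homer1 in other regions for DO mice and for CC083, the splits of the VTA and DO PFC libraries, and the fits without both choroid-rich PFC libraries were chosen only after the results they bear on had been seen.

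For 5 gene lists the difference between high and low performers was called as unequal in VTA and PFC of the same mice. The call was by a test of the interaction term (limma camera at the preset correlation, BH adjustment). With an estimated correlation or with fry 0 lists were called. As medians of VTA minus PFC, oligodendrocyte markers differed by -1.347 (lower in 24 of 24 genes, adjusted p = 2.51e-28; adjusted p = 0.469 with an estimated correlation). Choroid plexus and ependymal markers differed by -2.667 (lower in 17 of 18, adjusted p = 4.4e-05; adjusted p = 0.615 with an estimated correlation), a list whose level differed widely between single PFC libraries. Ionotropic glutamate receptor genes differed by 0.524 (higher in 24 of 28, adjusted p = 4.4e-05; adjusted p = 0.469 with an estimated correlation). Oxidative phosphorylation genes differed by -0.12 (lower in 57 of 68, adjusted p = 0.00377; adjusted p = 0.615 with an estimated correlation), a call lost without PFC high performer 1 (0.122), without VTA high performer 1 (0.312) and without both choroid-rich PFC libraries (0.278). Homer and postsynaptic scaffold genes differed by 0.314 (higher in 18 of 24, adjusted p = 0.0257; adjusted p = 0.615 with an estimated correlation), a call lost under quantile scaling (0.215), without PFC high performer 3 (0.313), PFC low performer 3 (0.107), VTA high performer 1 (0.373) or VTA low performer 1 (0.0934), and without both choroid-rich libraries (0.0556).

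The oligodendrocyte rise in PFC of high performers had the smallest p of the lists in that comparison. A general rise of oligodendrocyte RNA in these mice is argued against, because the score differed by 1.11 (SE 0.22) in PFC, by -0.18 (SE 0.27) in VTA and by 0 (SE 0.12) in mdTH, so PFC exceeded the larger of the other regions by 1.11. The mdTH libraries were of another class and batch than those of PFC, while the VTA libraries that carry this contrast were sequenced together with PFC. More white matter in the PFC punch stays open. The choroid plexus score of the same libraries was 9.47 and 7.87 in high performers and 4.69, 5.14 and 8.7 in low performers 1 to 3. Whether the dissection gave both this spread and the oligodendrocyte rise was not tested. Layer 6 and 6b markers, which border the white matter, exceeded upper layer markers by 0.58 (SE 0.32 over genes, mean 0.46 over 9 genes against -0.12 over 8). This is less than 2 SE and so undecided. A candidate biological explanation, more myelin in PFC of mice with high PPI, was not tested apart from the dissection, since both may give this value. For the DO PFC count of 24 genes the 10 splits of the libraries were too few for a share under 0.05; the real split was the 1 split of 10 that gave as many, and the highest other gave 9.

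Homer1 was lower in PFC of high-performing DO mice and of CC083, where PPI cannot be told apart from other differences between the lines. Excitatory cortical markers had a mean log2 fold change of 0.08 (SE 0.09 over genes) in DO PFC. In the CC lines it was 0.07 (SE 0.21 over genes, median -0.07). These values argue against a loss of excitatory neurons as large as the fall of Homer1. Genes are not independent replicates, and a loss of some neuron classes was not excluded. A sequence variant that loses Homer1 reads against the reference is argued against as the whole cause in the DO mice. The log2 fold change in mdTH exceeded that in PFC of the same mice by 1.61 (SE 0.2). The libraries of mdTH and PFC were of different classes and batches, and an effect of this on the difference was not tested. In VTA Homer1 was also lower without passing (-0.75, SE 0.29), not shown to differ from PFC. A variant in an isoform used in PFC was not separable. For CC083 a variant cannot be told apart, because 0 other regions of the CC lines were sequenced. The fastest activity-induced genes had a mean of -0.54 (SE 0.28 over genes, 7 of 11 below 0) in DO PFC. In the CC lines their mean was -0.93 (SE 0.09 over genes, 11 of 11). Lower neuronal activity before dissection stays open, as Homer1 also has an activity-induced isoform. A regulatory difference at Homer1 between high and low mice, a biological explanation, may act beside or instead of it and was not tested.

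Predicted genes and pseudogenes made up 37.5% of the CC calls. Low levels of these genes are argued against as the whole cause, because at a mean of at least 100 they were 116 of 403 calls (28.8%) against 7% of the genes tested, a ratio of 4.14. Reads shared between near-identical genes may contribute: called predicted genes shared most of their 31-mers with another gene in 55% of cases against 20% of those not called, an odds ratio of 4.09 over 10 level classes (95% interval 3.1 to 5.38, over genes, which are not independent; 98.3% of 3522 had values). Sequence differences between the lines in such copies, the biological difference the design names, were not tested and stay open.

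For the count of 654 genes in the CC lines the 10 splits were too few for a share under 0.05; the real split was the 1 that gave as many, and the highest other gave 0. The same holds for mdTH, where the real split gave 20 and was the 1 split with as many (highest other 2). In the CC, mdTH and DO PFC libraries every other split joins libraries of both real groups. A real difference then adds to its spread and lowers its count, so the gap in counts adds nothing. In VTA the real split gave 0, so all 10 splits necessarily gave as many (highest other 2), and their number decides nothing. For VTA against PFC, 100 of the 126 splits of the 10 libraries were drawn. Only the real split (1 of 100, a share under 0.05) gave 5750 genes with performance as a term, against 6 at most in the others. Every other split mixes the regions within its groups, so the region difference adds to its spread and lowers its count. The gap in counts therefore adds nothing to that share. Among the 16 splits that part the 2 libraries of all 5 mice the highest other gave 0.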

How the results depend on the processing

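The fits without both choroid-rich PFC libraries, with predicted genes left out, and with a meningeal, oligodendrocyte or dopamine score as a covariate were chosen after seeing the data; all other alternatives were planned. Leaving out a library of a pair assumes that the lone library varies like the other groups. The planned count test was not run for any of the 6 comparisons, since whole reads could not be recovered. Besides Homer1, direction was kept by all 44 named genes of the CC lines, all 12 passing named genes of mdTH, all 19 of DO PFC and all 115 of the regions in every alternative run, except that mt-Rnr1 in the CC lines was 0 under quantile normalisation. Of their values, 593 of 688, 80 of 154, 142 of 304 and 2118 of 2182 also kept their side of the threshold. Homer1 in the CC lines passed in 16 of 16 alternatives (-0.91 to -0.73, adjusted p = 0.00361 to 0.0468 by limma with BH adjustment). It never passed in VTA (-0.98 to -0.49) or mdTH (0.06 to 0.31). In DO PFC it passed in 11 of 16 (leave-one-out -1.59 to -1.25) and missed without trend or robust variances (-1.42, adjusted p = 0.38), with the replicate block (-1.46, 0.11), in the joint fit of PFC and VTA (-1.42, 0.139) and without low performer 1 (-1.38, 0.0832), and the cause was not tested. With the oligodendrocyte score as a covariate it was -1.24 (0.634); its SE grew from 0.13 to 0.38, as the score followed the groups at r = 0.94 and 2 residual degrees of freedom were left.

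The count of 654 in the CC lines became 403 at a mean of at least 100 and 316 without predicted genes (fewer genes tested), and 351 to 591 when a library was left out; with the meningeal covariate it was 616, and with the replicate block 471. In mdTH the count of 20 became 68 without a filter, 4 without trend or robust variances (Gpr26, Igfbpl1, Wfdc10 and Gm4294), 0 with the replicate block and 1 to 11 when a library was left out. In DO PFC the count of 24 became 131 without a filter, 0 without trend or robust variances, 1 with the replicate block (Rps26-ps1), 7 in the joint fit, 0 with the oligodendrocyte covariate and 1 to 86 when a library was left out. In VTA the count of 0 became 3 with the block and batch (Rps26-ps1, Gm15772 and AY036118), 1 without the batch term (AY036118), 1 in the joint fit (Gm15772), 2 with the dopamine covariate (Gm15772 and Gm8172) and 0 to 1 when a library was left out (Rps26-ps1 without low performer 2). For the regions 5260 became 3334 without both choroid-rich libraries (fewer samples) and 3890 to 5607 when 1 was left out. For the interaction 0 became 1 without PFC high performer 3 (AY036118) and 1 without VTA high performer 1 (Pcdhgb8), with a range of 0 to 1. Catspere2 in VTA turned to -0.01 (adjusted p = 0.999, over its alternatives 0.692 to 1) without the batch term. For all counts but those with fewer genes or samples the cause was not tested.

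With an estimated correlation 0 lists passed in any of the 6 comparisons, and with fry 0 in the CC lines, mdTH, VTA and the interaction, 1 in DO PFC and 19 for the regions. When a library was left out, 5 to 12 lists passed in the CC lines (8 in full), 2 to 10 in mdTH (8), 7 to 15 in DO PFC (11), 0 to 9 in VTA (6), 15 to 22 for the regions (18; 22 with the mouse block) and 4 to 10 for the interaction (5; 6 with the mouse block). Quantile scaling left 4 lists in mdTH and 2 in VTA, 75th percentile scaling 2 in VTA, and the replicate block 3 in mdTH. The share of CC calls with the same sign in DO PFC was 50.3% and 55% in its 2 alternatives. Depth was about 33.2 M to 80.6 M reads per library. Genes with a mean under 10 were not tested, and counting error could not be separated from the spread between mice.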

Other observations

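The test of whether called genes lie near one another was written down before its result was seen, but its repeat without predicted genes, and the weight given to that repeat, were not.

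Single members of 4 gene lists that did not pass between VTA and PFC of the DO mice changed, in both directions. Of 21 GABA receptor genes, 4 rose and 8 fell in VTA (limma camera with BH adjustment for the list, adjusted p = 0.0921). Gabrq, the theta subunit, was at 1006 ± 135.4 in VTA and 34.81 ± 10.61 in PFC (n = 5 each, log2 fold change 4.81, limma with BH adjustment, adjusted p = 5.5e-07), and Gabrd, the delta subunit, at 107.3 ± 88.39 against 1603 ± 315.6 (-4.27, adjusted p = 1.46e-05). Of 32 monoamine and acetylcholine receptor genes, 6 rose and 13 fell (camera adjusted p = 0.089). Chrm1, a muscarinic receptor, was at 300.5 ± 89.96 against 6411 ± 708 (-4.43, adjusted p = 1.97e-07), Adra1d, an adrenergic receptor, had -4.21, and Htr2c, the serotonin receptor that rose in PFC of high performers, was higher in VTA (4537 ± 590.8 against 1589 ± 895.1, 1.54, adjusted p = 1.12e-05). Of 17 glucocorticoid-responsive genes 5 rose and 3 fell (camera adjusted p = 0.562), with Klf9 (-1.21) and Zbtb16 (-1.36) lower and Mt2, a metallothionein, higher (0.89) in VTA. Of 69 genes within 5 Mb of Homer1, 18 rose and 14 fell (camera adjusted p = 0.686), among which Enc1 fell (2956 ± 564.8 against 26460 ± 7405, -3.06, adjusted p = 2.65e-07) and F2r, the thrombin receptor, rose (3662 ± 1925 against 309.6 ± 78.62, 3.52, adjusted p = 6.96e-05).

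VTA high performer 2, from its own batch, held 969 normalised counts of Homer1, below the 2056 to 3772 of the low performers. Its mitochondrial ribosomal RNA was 0.68% against 29.14% to 37.54% in the other VTA libraries, and the small cytoplasmic RNAs Rn7s and Rn7sk took 0.001% of its signal against 4.906% to 6.804% in the others. The same difference held between mdTH libraries and all CC and DO PFC libraries, although all are described as made with 1 kit for mRNA.

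One hypothesis was that CC calls cluster in blocks of the genome in which the lines differ in DNA sequence. Of 648 calls with a position, 57.4% had another call within 1 Mb, but random sets of tested genes already gave a median of 55.1% and up to 61.4% in 1000 draws. As many as 140 of these sets reached the share of the calls, and the bound written beforehand, any value inside the range of the random sets, would count this against the hypothesis. Without predicted genes the share was 52%, against a median of 43.4% and at most 52.9% in random sets, of which 4 of 1000 were as high. That value also lies inside the range, so the bound was too wide to exclude clustering, and clustering cannot be told apart from its absence here.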
